A study of Solanum pimpinellifolium with 56 samples.

How the data were processed

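Developing fruits of wild tomato (Solanum pimpinellifolium, accession LA1589) were compared with those of a near-isogenic line (NIL), a line bred to differ from its parent in a short donor segment, here the one carrying the SUN fruit shape locus. Per the labels' protocols, plants grew in a greenhouse, several fruits made up a sample, and each fruit was stored in RNAlater, dissected under a microscope and extracted with Trizol. The columella part held columella and septa, the seed part held seeds and placenta, and the pericarp part held the rest of the fruit. Libraries were of the 3′ tag kind, in which reads start near the end of a transcript, so that a read stands for a transcript without regard to its length. Fruits were taken at 2, 4, 6, 8 and 10 days post anthesis (dpa), with no columella samples at 6 dpa, which gave 28 groups of 2 replicates and 56 libraries. Nothing in the labels says whether replicates came from separate plants, so p-values measure the spread between these samples only. Groups and replicate numbers were read from the sample titles.

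The authors deposited 1 table of values for 35768 Solyc identifiers, and its name calls them TPM. The deposited values are CPM, reads scaled to a common library total and not divided by gene length. Every column summed to that total, and within a column the values were whole multiples of 1 step that was the same for all identifiers, as it is for CPM. Dividing by that step gave back whole reads: at least 99.852% of the values above 0 in each library lay within 0.05 of a whole number. Recovered depth ranged from 180921 reads (wild type columella, 2 dpa, replicate 2) to 17893909 reads (SUN NIL columella, 10 dpa, replicate 1), 186998924 reads over all libraries. Per the submitters' processing notes, Trimmomatic, cutadapt and HISAT2 were used, with no versions; the genome build, annotation and counting tool are not given in the sources used here. Whether the counting used strand, and how it treated reads that match several places, is also not given, so overlapping genes and near-identical copies cannot be separated with these values. PCR copies could not be removed without molecular tags, so read-based limits cover counting error only. A gene with no read in a library can lie at up to 3 reads, which is 16.6 CPM in the shallowest library and 0.168 CPM in the deepest.

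Values were tested as log2(CPM + 1) for the 18020 identifiers with a mean of at least 1 CPM over all libraries; 6965 identifiers had no read in any library. Differences on this scale understate the change of low genes. limma 3.58.1 in R 4.3.3 fitted the 28 group means to all 56 libraries (28 residual degrees of freedom), with moderated variances (trend, robust), and p-values were adjusted over all tested identifiers by the Benjamini-Hochberg method, with 0.05 as the threshold. The contrasts were SUN NIL against wild type in each tissue (mean over days), the same at each of the 14 combinations of tissue and day, the difference of the genotype effect between tissues and between late (8 and 10 dpa) and early (2 and 4 dpa) fruits, each pair of tissues (mean over both genotypes and over 2, 4, 8 and 10 dpa), and 10 against 2 dpa in each tissue. In the text, a gene "rose", "fell" or "was called" only if it passed this threshold. Position was tested with Fisher's exact test, two-sided, on the chromosome number within each identifier. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

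The deposited table pairs no identifier with a gene name, and 0 of its identifiers matched the reference table given (assembly ASM5822483v1), so 41 lists defined by gene descriptions could not be matched and are not reported. A list of 7 fruit shape and size genes, defined by identifier with names from general knowledge of tomato, was used. It had 4 tested members, fewer than the 5 set as the minimum for a gene set test, so its members are reported singly, and no set test (camera, fry) was run. Outside that list, identifiers were named by a rule: among those called, with a mean of at least 5 CPM in the libraries compared, those with the largest log2 difference. The rule asked for the same direction at every day in genotype comparisons, in both genotypes between days, and in both genotypes at every day between tissues. It allowed more genes where a source names them and, with no names in any source, 2 identifiers per direction, which is what was used. Where a genotype comparison called 5 or fewer identifiers in a direction, the others are also named, which was decided after their values were seen. The list, the contrasts, the naming rule and the alternatives, apart from those added later, were fixed before the data were examined.

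Alternatives covered the pseudocount (0.25 and 5), the low-value filter (none, and a mean of 5 CPM), trimmed mean (TMM) scaling, quantile normalization, sample quality weights, non-robust moderation, the replicate number as a fixed block and with genotype and day as a random block, an adjusted p threshold of 0.1 for position and overlap, fits of only the samples compared, wild type alone, and each library left out in turn. After the data were seen, edgeR 4.0.16 (quasi-likelihood test on the recovered reads), limma voom on those reads, and a fit without 2 doubted wild type columella libraries were added, as were contrasts of consecutive days, a test of position without SUN, a share with each day left out, and TMM counts of identifiers that differ from both other tissues. The main test was also tested on simulated counts for all 18020 genes, 100 of them changed 2-fold and 100 changed 4-fold in each comparison. The changed genes were drawn only from those with a mean of at least 5 CPM, so the recovery does not cover lower genes. For the genotype contrasts it recovered 73% of the genes changed 2-fold and 96% of those changed 4-fold in pericarp. The shares were 71% and 95% in columella, and 75% and 98% in seeds. It called 7, 9 and 18 unchanged genes in these contrasts, among 176, 175 and 191 calls. For the tissue contrasts it recovered at least 92% of the 2-fold changes and called 11 to 13 unchanged genes, among 203 to 208 calls. For 10 against 2 dpa it recovered 37%, 38% and 28% of the 2-fold changes in pericarp, columella and seeds. Of the 4-fold changes it recovered 87%, 92% and 88%. It called 7, 30 and 14 unchanged genes in these tissues, among 131, 160 and 130 calls. Replicates differed by more than sampling noise in every group (chi-square per degree of freedom at least 2.24). PCR copies could add to this, so it does not show that replicates were separate samples. They were counted as separate by their titles.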

Results

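Transcript levels were measured by 3′ tag sequencing in pericarp, columella and seeds of wild type and SUN NIL fruits at 2, 4, 6, 8 and 10 dpa, with no columella at 6 dpa, in 56 libraries (n = 2 per genotype, tissue and day). SUN encodes a protein of the IQD family, and its raised expression elongates tomato fruits. Median depth per tissue and genotype lay between 1932185 reads (SUN NIL pericarp, 10 libraries) and 2845933.5 reads (wild type pericarp, 10 libraries). The shallowest library, wild type columella at 2 dpa replicate 2, held 180921 reads, so that 1 of its reads is worth more CPM than in any other. Day and tissue set the main differences between libraries. The first principal component held 27.9% of the variance, of which day explained 72.4%, and the second held 23.3%, of which tissue explained 73.4%. Genotype explained at most 0.0326% of either.

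**Figure D1:**
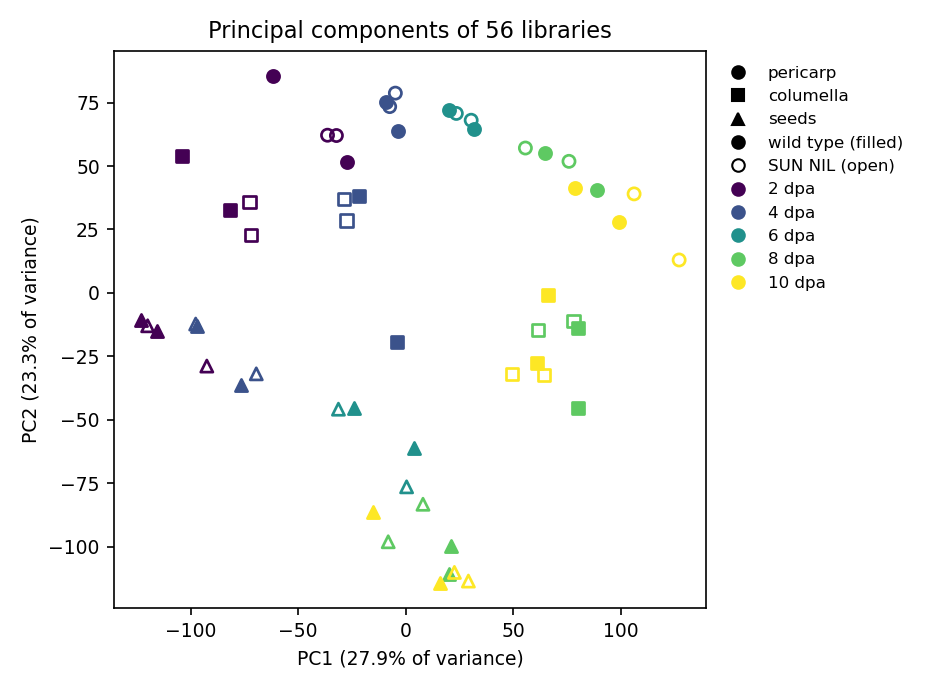
Principal components of the log2(CPM + 1) values of the 56 libraries, with PC1 (27.9% of variance) on the x axis and PC2 (23.3%) on the y axis. Symbols mark tissue, colours mark dpa, and filled and open symbols mark wild type and SUN NIL. Day explained most of PC1 and tissue most of PC2, but days overlap along PC1 and tissues along PC2.

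The first comparison checked the labels through SUN itself. The SUN identifier, Solyc10g079240, was higher in SUN NIL than in wild type in all tissues, and each SUN NIL library lay above the wild type libraries of its tissue and day. The difference was small in seeds at 10 dpa, at 30.2 ± 10.9 against 13.4 ± 8.65 CPM (SD, n = 2 each), where SUN did not pass. In pericarp it averaged 169 ± 88.2 CPM (SD, n = 10) in SUN NIL and 4.14 ± 4.46 CPM (SD, n = 10) in wild type, a ratio of 40.8 (log2 difference 5.30, SE 0.24, limma adjusted p = 4.62e-19). In columella it averaged 45.0 ± 15.8 CPM (SD, n = 8) against 1.61 ± 1.81 CPM (SD, n = 8), a log2 difference of 4.36 (SE 0.27, limma adjusted p = 3.02e-14). In seeds it averaged 37.7 ± 13.8 CPM (SD, n = 10) against 3.99 ± 5.84 CPM (SD, n = 10), a log2 difference of 3.48 (SE 0.24, limma adjusted p = 6.12e-13). The lowest SUN NIL library held 17.0 CPM and the highest wild type library 19.5 CPM, both in seeds. In SUN NIL pericarp the level was 95.7 ± 14.6 CPM at 2 dpa and 80.4 ± 51.4 CPM at 10 dpa (SD, n = 2 each), and at 8 dpa the replicates held 306 and 213 CPM.

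**Figure D2:**
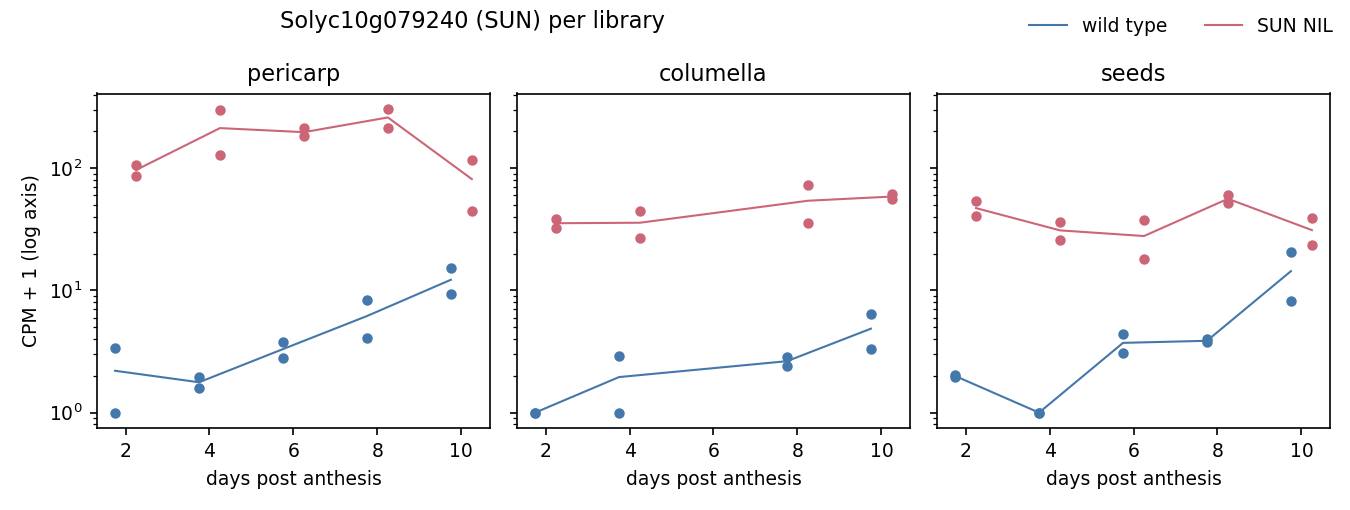
CPM + 1 of Solyc10g079240 (SUN) on a log axis against dpa in each tissue. Points are single libraries and lines join the means of 2 replicates; every SUN NIL library lies above the wild type libraries of its tissue and day, and wild type is highest at 10 dpa, with means of 11.2 CPM in pericarp and 13.4 CPM in seeds.

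In wild type alone SUN was also higher at 10 than at 2 dpa. The log2 difference was 2.68 (SE 0.54, limma adjusted p = 0.00018) in pericarp and 2.71 (SE 0.54, limma adjusted p = 0.000159) in seeds. Wild type means at 2 dpa were 1.20 CPM in pericarp and 0.996 CPM in seeds (n = 2 each), close to the level of single reads, so these log2 differences depend on the pseudocount. In columella both wild type libraries at 2 dpa held 0 reads of SUN, against 5.40 and 2.33 CPM at 10 dpa (limma adjusted p = 0.00141). Of these, replicate 2 at 2 dpa held 180921 reads in all, too few for 0 reads to show a level below those at 10 dpa. The columella difference therefore rests on replicate 1 at 2 dpa.

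The next question was which other transcripts differ between the lines. In pericarp 8 of 18020 tested identifiers passed, 4 higher and 4 lower in SUN NIL; in columella 6 passed, 3 in each direction, and in seeds 4 passed, 2 in each direction. At an unadjusted limma p under 0.05 the counts were 483, 1094 and 342, and edgeR on the recovered reads called 8, 5 and 4. On chromosomes 10 and 7, 4 identifiers passed in all 3 tissues: SUN and Solyc10g079250 were higher, and Solyc07g007750 and Solyc07g007760 were lower. Solyc10g079250, next to SUN in identifier order, rose from 5.49 ± 1.34 to 45.3 ± 16.0 CPM (SD, n = 10 each) in pericarp (log2 difference 2.78, SE 0.19, limma adjusted p = 1.33e-13). Its log2 difference was 1.18 (SE 0.21, limma adjusted p = 0.00558) in columella and 1.59 (SE 0.19, limma adjusted p = 1.29e-06) in seeds.

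The largest falls were of abundant transcripts. Solyc07g007750 fell from 8465 ± 2489 to 555 ± 394 CPM (SD, n = 10 each) in pericarp, a log2 difference of -4.30 (SE 0.18, limma adjusted p = 6.54e-20). In columella it fell from 8616 to 908 CPM (log2 difference -3.14, SE 0.20) and in seeds from 5102 to 381 CPM (log2 difference -3.36, SE 0.18). Solyc07g007760 fell from 3361 ± 874 to 86.6 ± 102 CPM (SD, n = 10 each) in pericarp, a log2 difference of -5.94 (SE 0.35, limma adjusted p = 4.88e-14). In columella its log2 difference was -6.09 (SE 0.40) and in seeds -3.78 (SE 0.35). Both had the same direction at each of the 5 days in pericarp and seeds and each of the 4 days in columella.

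Smaller changes passed in fewer tissues; those named here were chosen after their values were seen, except Solyc09g005570 in columella. Solyc09g005570 was higher in SUN NIL in pericarp (log2 difference 1.81, SE 0.25, limma adjusted p = 3.99e-05) and in columella (1.66, SE 0.28, limma adjusted p = 0.00292); in seeds its value was 0.12 (SE 0.25, limma adjusted p = 1). Solyc10g079210 was higher in pericarp (1.68, SE 0.21, limma adjusted p = 6.16e-06), from 0.783 to 4.67 CPM, and its values in columella and seeds were 0.17 and 0.24. Solyc11g071205 was lower in pericarp (-1.15, SE 0.20, limma adjusted p = 0.0025) and columella (-1.30, SE 0.22, limma adjusted p = 0.00292), where wild type averaged 2.62 and 3.69 CPM; edgeR called it in pericarp and not in columella (log2 difference -3.37, adjusted p = 0.437, range over its columella alternatives 0.000262 to 0.437). Solyc12g082720 was lower in pericarp (-1.36, SE 0.25, limma adjusted p = 0.0105), and its value in seeds was -1.08 (SE 0.25, limma adjusted p = 0.475). That pericarp call was lost (limma adjusted p between 0.0521 and 0.0807) without any 1 of 8 libraries: wild type at 2 dpa replicate 2, 6 dpa replicate 1, 8 dpa replicate 2 and 10 dpa replicate 1, and replicate 2 of SUN NIL at 4, 6, 8 and 10 dpa. In a fit of the columella libraries alone the calls of Solyc09g005570, Solyc10g079250 and Solyc11g071205 were lost, leaving 3, and voom lost Solyc09g005570 there (adjusted p = 0.0608, range over its alternatives 9.34e-06 to 0.527). Without SUN NIL columella at 10 dpa replicate 2, Solyc10g079250 was lost there (limma adjusted p = 0.0502, range over its alternatives 0.00176 to 0.0709). Left-out wild type columella libraries also moved that count: it was 596 without 2 dpa replicate 1 and 27 without 4 dpa replicate 2.

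A near-isogenic line carries donor DNA around its locus, so the position of the calls was examined. The SUN identifier belongs to chromosome 10, and the locus in the NIL is known as a copy of that region inserted on chromosome 7. Of the 8 identifiers called in any tissue, 3 were on chromosome 10 and 2 on chromosome 7, the remaining ones being on chromosomes 9, 11 and 12. In pericarp the share on chromosome 10 exceeded that of other tested identifiers (3 of 8 calls, Fisher's exact p = 0.0135), and the share on chromosome 7 did not pass (2 of 8, Fisher's exact p = 0.118). In columella neither passed (2 of 6 calls each, Fisher's exact p = 0.0574 for chromosome 10 and p = 0.0702 for chromosome 7), though at an adjusted p threshold of 0.1 chromosome 7 held 3 of 7 calls (Fisher's exact p = 0.0121). In seeds both did (2 of 4 calls each, Fisher's exact p = 0.0251 and p = 0.0311). SUN is itself on chromosome 10 and defines the line; without it no tissue passed there, with 2 of 7 calls in pericarp, 1 of 5 in columella and 1 of 3 in seeds (Fisher's exact p = 0.0767, 0.296 and 0.19), a test added after the data were seen. All these p-values count neighbours as independent, and with SUN 12 tests were made, 6 at each threshold. Solyc07g007750 and Solyc07g007760 are consecutive identifiers, and the tested identifiers on either side of them were not called; Solyc07g007745 had log2 differences of 0.04, -0.05 and -0.07 and Solyc07g007780 of -0.15, 0.18 and 0.02 in pericarp, columella and seeds. Likewise Solyc10g079200 (0.02, 0.09 and 0.11) and Solyc10g079260 (0.46, 0.01 and 0.07), which enclose the called stretch on chromosome 10, did not pass, and Solyc10g079220, Solyc10g079230 and Solyc10g079233 within it had too few reads to test. No coordinates or genome build are given with the identifiers.

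**Figure D3:**
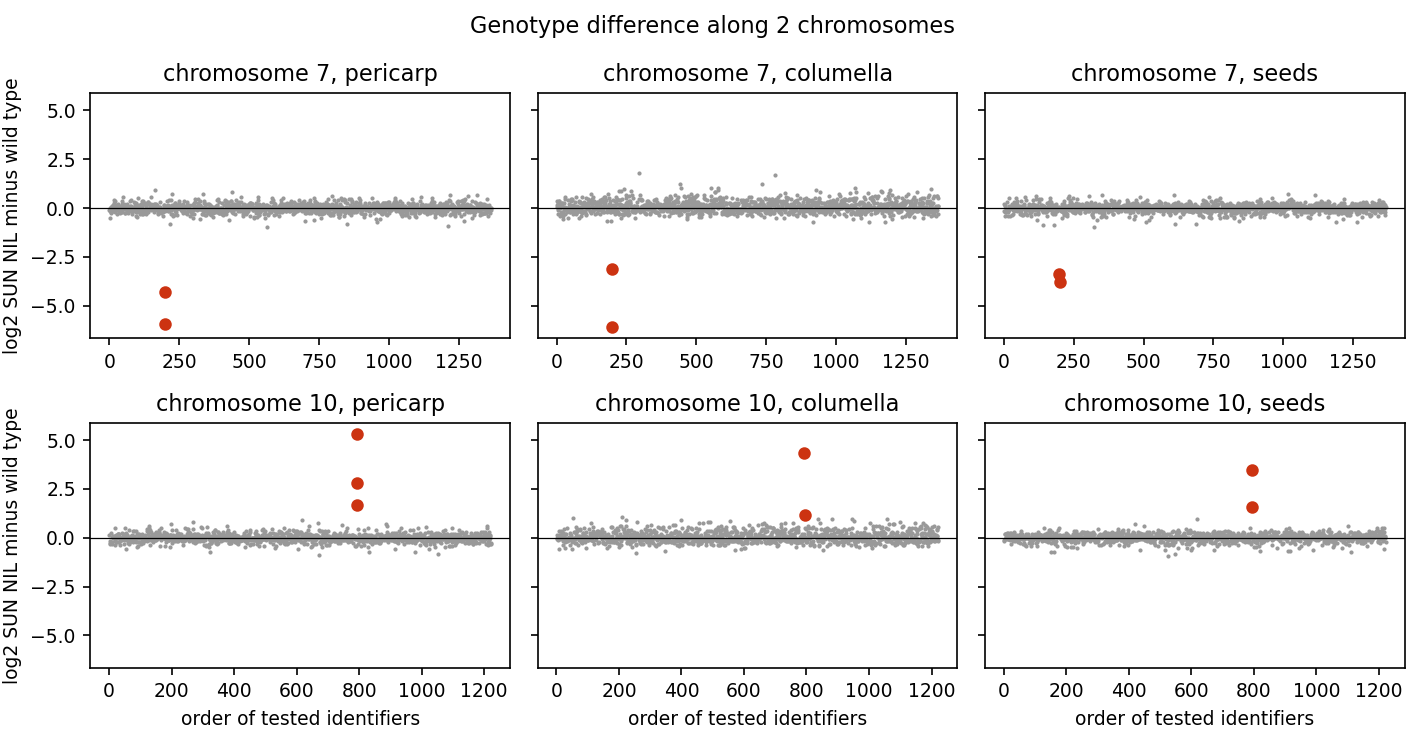
Log2 difference between SUN NIL and wild type (y axis, mean over days) of each tested identifier on chromosomes 7 and 10, in identifier order (x axis), for each tissue. Red points passed the limma threshold: 2 neighbouring identifiers on chromosome 7 lie below 0 in every tissue, and 3 (pericarp) or 2 (columella, seeds) identifiers on chromosome 10 lie above it.

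Single days added few genes outside columella at 2 dpa. The 14 comparisons of 2 against 2 libraries gave 178 calls of 141 identifiers. Columella at 2 dpa gave 131 of these calls, 126 of them higher in SUN NIL, and every other combination gave between 0 and 6. That comparison included the shallowest library, in which 113 of the 126 identifiers had no read; without it 3 identifiers were called, and without the other wild type replicate 3274. edgeR called 3 there and voom 1, though voom called 139 in columella at 10 dpa, where limma called 6. Without that library and wild type columella at 4 dpa replicate 1, the 14 comparisons gave 58 calls in all. In seeds at 10 dpa limma, edgeR and voom called 0 identifiers, with 1412 and 1462 at an unadjusted p under 0.05 in limma and edgeR.

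Differences of the genotype effect between tissues and between days were tested next. No identifier passed for any pair of tissues with limma, with 281 (seeds minus pericarp), 878 (columella minus pericarp) and 742 (seeds minus columella) at an unadjusted p under 0.05; edgeR called 1, 2 and 0, with 420, 970 and 679, and voom called 1, 0 and 0. For SUN the effect was smaller in seeds than in pericarp by 1.82 on the log2 scale (value -1.82, SE 0.34), which missed the threshold over all genes (limma adjusted p = 0.0814) and passed adjusted over the list alone (limma adjusted p = 1.81e-05). edgeR gave -1.04 for the same difference and an adjusted p of 1 over the list alone; over all genes the adjusted p ranged from 8.45e-05 to 1 over the alternatives and passed in 11 of 54. On the log2 scale the SUN effect was also smaller in late than in early fruits in pericarp and seeds, adjusted over the list alone and not over all genes. In CPM the SUN difference between genotypes was largest at 8 dpa in both tissues (254 CPM in pericarp and 52.4 CPM in seeds). Between early and late fruits, Solyc07g007750 in pericarp was the 1 identifier that passed: its fall in SUN NIL was stronger at 8 and 10 dpa by a log2 difference of -2.44 (SE 0.40, limma adjusted p = 0.00888). In SUN NIL pericarp it went from 871 CPM at 2 dpa and 1025 CPM at 4 dpa to 164 CPM at 8 dpa and 181 CPM at 10 dpa, against 6187, 10758, 8816 and 6944 CPM in wild type (n = 2 each). The call was lost with edgeR (log2 difference -2.32, adjusted p = 0.104), with quantile normalization (0.364) and in a fit of pericarp alone (0.315), a range of 0.000268 to 0.364 over all alternatives. It was also lost (limma adjusted p between 0.0549 and 0.105) without any 1 of 7 pericarp libraries: wild type at 2 dpa replicate 2, 8 dpa replicate 1 and 10 dpa replicate 2, and SUN NIL at 2 dpa replicate 2, 4 dpa replicate 1, 8 dpa replicate 1 and 10 dpa replicate 1. In columella and seeds 0 identifiers passed with limma, edgeR or voom, with 1022 and 176 at an unadjusted p under 0.05 in limma and 551 and 251 in edgeR.

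The list of fruit shape and size genes held 7 identifiers, of which 4 were tested. Besides SUN these were OVATE (Solyc02g085500), the founding member of a family of growth regulators, WUS at the LC locus (Solyc02g083950), a homeodomain transcription factor of the stem cell niche, and KLUH at the FW3.2 locus (Solyc03g114940). Of the 4, SUN alone differed between genotypes in each tissue, both over all genes and adjusted over the list alone. The limma adjusted p of OVATE, WUS and KLUH was at least 0.793 over all genes in every tissue. The FW2.2 identifier (Solyc02g090730) had 0 reads in all 56 libraries, which allows up to 0.0160 CPM over the series, counting error only. Its name comes from general knowledge, and whether reads of the FW2.2 gene were counted on it could not be checked, so this limit belongs to the identifier. CLV3 (Solyc11g071380) had 28 reads and CSR (Solyc11g071940) 23 reads in all libraries together, too few to test.

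Between tissues 3 of the 4 tested members were called in each comparison, over all genes and adjusted over the list alone. From 2 to 10 dpa 4 were called in columella and seeds either way, and in pericarp 2 over all genes and 3 adjusted over the list alone. Several of these calls depended on 1 choice. In edgeR, WUS was not called between seeds and pericarp or seeds and columella (adjusted p = 1 each; ranges over alternatives 1.42e-12 to 1 and 2.22e-10 to 1), although its log2 differences there were 2.29 and 0.99, against 1.41 and 1.05 in limma. In wild type alone, SUN was not called between seeds and pericarp (-0.29, limma adjusted p = 0.421, range over alternatives 3.93e-07 to 0.421). WUS between 10 and 2 dpa in columella was lost in a fit of columella alone (limma adjusted p = 0.0529, range over alternatives 8.52e-05 to 0.0529).

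The SUN calls between 10 and 2 dpa over both genotypes rest on the log2 scale. Their log2 differences were 1.14 (SE 0.38, limma adjusted p = 0.0137) in pericarp and 1.04 (SE 0.38, limma adjusted p = 0.0248) in seeds, while the ratio of mean CPM was 0.946 and 0.924. The means of the genotypes moved in opposite directions and towards each other: between 2 and 10 dpa SUN NIL went from 95.7 to 80.4 CPM in pericarp and from 46.1 to 30.2 CPM in seeds, and wild type from 1.20 to 11.2 CPM and from 0.996 to 13.4 CPM. In pericarp the call was lost with a pseudocount of 5 (0.134) and in a fit of pericarp alone (0.0581). It was also lost without wild type at 2 dpa replicate 1 (0.157), wild type at 10 dpa replicate 1 (0.0687) or SUN NIL at 10 dpa replicate 1 (0.121), with a range of limma adjusted p of 0.00018 to 0.157 over alternatives. In seeds it was lost with a pseudocount of 5 (0.148) and with voom (0.0533). It was also lost without wild type at 2 dpa replicate 1 (0.0546) or replicate 2 (0.0505), SUN NIL at 2 dpa replicate 1 (0.0777), or replicate 1 at 10 dpa of wild type (0.167) or SUN NIL (0.108), with a range of 0.000159 to 0.167.

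The other members differed more clearly by tissue and day. KLUH was highest in seeds, at 893 ± 261 CPM at 2 dpa and 215 ± 97.0 CPM at 10 dpa (SD, n = 4, both genotypes), and lower in columella, at 126 ± 33.1 CPM and 22.7 ± 12.6 CPM. In pericarp it was 5.37 ± 3.24 CPM at 2 dpa and 2.95 ± 4.07 CPM at 10 dpa. The log2 difference between seeds and pericarp was 7.09 (SE 0.27, limma adjusted p = 1.58e-21), and between columella and pericarp 3.23 (SE 0.27, limma adjusted p = 6.46e-12). KLUH fell from 2 to 10 dpa in seeds (-2.16, SE 0.54, limma adjusted p = 0.00151) and columella (-2.52, SE 0.54, limma adjusted p = 0.00029). WUS was highest in seeds at 2 dpa, at 34.2 ± 7.98 CPM (SD, n = 4), and averaged 1.77 CPM at 4 dpa and 0.191 CPM at 6 dpa there. In columella at 2 dpa it averaged 2.88 ± 2.43 CPM (SD, n = 4). The highest value there, 5.53 CPM, is a single read of the shallowest library. The fall of WUS from 2 to 10 dpa in seeds was -5.01 on the log2 scale (SE 0.36, limma adjusted p = 3.2e-14). OVATE was highest in columella at 2 dpa, at 48.1 ± 15.2 CPM (SD, n = 4), against libraries between 10.3 and 12.6 CPM in pericarp and 8.20 ± 4.72 CPM in seeds. It fell from 2 to 10 dpa in all tissues, by a log2 difference of -3.24 in columella (SE 0.38, limma adjusted p = 7.03e-09), -1.80 in pericarp (SE 0.38, limma adjusted p = 0.000159) and -1.78 in seeds (SE 0.38, limma adjusted p = 0.000203). Averaged over days it was higher in columella than in pericarp (0.83, SE 0.19, limma adjusted p = 0.000545), a call not reached in wild type alone (0.58, limma adjusted p = 0.11).

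**Figure D4:**
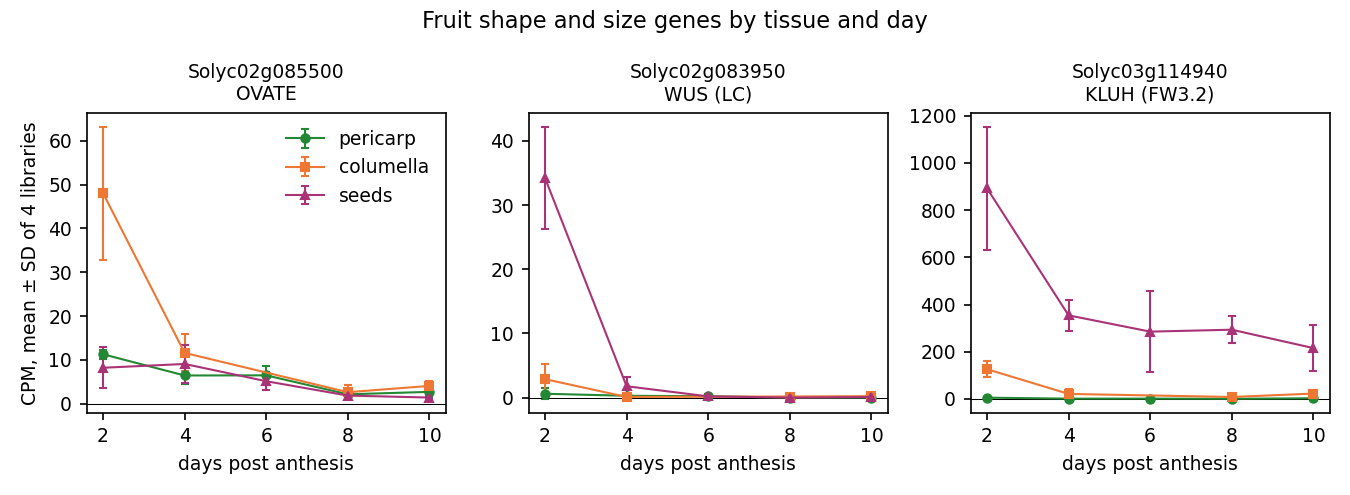
CPM (y axis) of OVATE, WUS and KLUH against dpa (x axis) in pericarp, columella and seeds. Points are means of 4 libraries, 2 of each genotype, and bars are SD; KLUH and WUS are highest in seeds at 2 dpa (893 and 34.2 CPM) and OVATE in columella at 2 dpa (48.1 CPM).

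Tissues differed in far more genes than genotypes. Between seeds and pericarp 10038 of 18020 identifiers passed, 6806 higher and 3232 lower in seeds. Solyc01g108450 averaged 2762 ± 959 CPM in seeds and 12.5 ± 11.2 CPM in pericarp (SD, n = 16 each; log2 difference 7.92), and Solyc04g078730 averaged 813 and 4.09 CPM. In the other direction Solyc07g008180 averaged 7.38 CPM in seeds and 811 CPM in pericarp (log2 difference -6.91, SE 0.24), and Solyc10g075090 averaged 17.1 and 3617 CPM. The median of all tested genes lay at 0.21 in this contrast. With TMM scaling, which moved that median to 0.02, 4457 were higher and 4492 lower, so the surplus of genes higher in seeds depends on the scaling.

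Between columella and pericarp 7038 identifiers passed, 5298 higher and 1740 lower in columella, or 2960 and 2606 with TMM scaling (median of all genes 0.19, and 0.01 with TMM). In wild type alone 4447 passed. Solyc03g097560 averaged 211 ± 98.6 CPM in columella and 6.14 ± 4.34 CPM in pericarp (SD, n = 16 each; log2 difference 5.00, SE 0.22), and Solyc05g051820 averaged 38.8 and 0.552 CPM. Solyc10g075090, low in seeds, was also low in columella, at 45.7 against 3617 CPM in pericarp (log2 difference -5.55), and Solyc12g011040 averaged 3.78 and 176 CPM. Between seeds and columella 7327 identifiers passed, 3628 higher and 3699 lower in seeds. Solyc04g078730 and Solyc01g108450 were higher in seeds here too (log2 differences 5.24 and 5.18), and Solyc08g082190 and Solyc02g081120 were lower (-4.54 and -4.45). Counted over the comparisons with both other tissues, 3119 identifiers were higher in seeds than in either, 1354 in pericarp and 1621 in columella, and 2169, 3476 and 363 were lower. These counts depend on the scaling: with TMM, added here after the data were seen, 2684, 2044 and 1197 were higher and 2675, 1770 and 499 lower. Both comparisons of a tissue share its libraries.

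Between 2 and 10 dpa the transcriptome of every tissue was remodelled. In pericarp 7818 identifiers passed, 3565 higher and 4253 lower at 10 dpa (4117 and 3810 with TMM scaling). Solyc01g111145 rose from 4.41 ± 1.18 to 3006 ± 206 CPM (SD, n = 4 each) and Solyc05g055400 from 5.28 to 3022 CPM, while Solyc01g006390 fell from 490 to 0.377 CPM and Solyc09g089530 from 813 to 2.13 CPM. In columella 8364 passed, 3769 higher and 4595 lower (5084 and 3040 with TMM). There Solyc04g071610 rose from 113 ± 22.9 to 28902 ± 5000 CPM (SD, n = 4 each; log2 difference 7.99, SE 0.25, limma adjusted p = 8.47e-25), and Solyc03g116225 from 0.463 to 351 CPM. Solyc01g091050 fell from 122 to 0.0425 CPM and Solyc06g064820 from 1022 to 10.2 CPM. In seeds 7910 passed, 3156 higher and 4754 lower (4330 and 3018 with TMM). Solyc02g068620 rose from 0.847 to 2047 CPM and Solyc05g051260 from 13.7 to 9910 CPM, and Solyc03g007780 fell from 1762 to 0.395 CPM and Solyc02g084980 from 1340 to 0.406 CPM. With TMM scaling the median of all genes moved from -0.09 to 0.17 in columella and from -0.19 to 0.07 in seeds. In wild type alone 4524 passed in pericarp and 4666 in seeds.

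The changes with day overlapped between tissues. Pericarp and columella shared 2167 identifiers higher at 10 dpa and 2819 lower, where independent lists would share 746 and 1084.5. Pericarp and seeds shared 1587 and 2381 (624 and 1122 for independent lists), and columella and seeds shared 2130 and 3127 (660.1 and 1212). In all tissues 1371 were higher and 2063 lower. The counts for independent lists assume that every identifier is equally likely to be called. These overlaps are given for the main scaling only, and the counts in each direction depend on the scaling. Contrasts of consecutive days, added after the data were seen, called few genes between 8 and 10 dpa in columella and seeds. In columella 4555 identifiers passed between 2 and 4 dpa, 5139 between 4 and 8 dpa, a step of 4 days, and 644 between 8 and 10 dpa. The columella step from 2 to 4 dpa includes the shallowest library. Both steps before 8 dpa include wild type columella at 4 dpa replicate 1, the other doubted library, and their counts are given with these libraries only. In seeds 3263 passed between 2 and 4 dpa, 3672 between 4 and 6 dpa, 1312 between 6 and 8 dpa and 571 between 8 and 10 dpa. In pericarp the counts were 1257, 609, 1057 and 1012 for the 4 steps from 2 to 10 dpa.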

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

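The tests of reads counted on neighbours, of sequence differences, of older fruits, of seed material and of the genotype effect at 2 dpa, and the edgeR values, were chosen only after the results were seen. Some differences between effects stood out. The genotype effect on Solyc07g007750 in pericarp differed between late and early fruits (log2 difference of effects -2.44, limma adjusted over all genes). For SUN (Solyc10g079240) 3 differences passed over the list alone: seeds minus pericarp (-1.82), late minus early in pericarp (-2.21) and late minus early in seeds (-2.20). Both day differences hold on the log2 scale, and in CPM the difference between the genotypes was largest at 8 dpa in both tissues. With edgeR the 2 day differences of SUN passed over the list alone (-3.06 and -4.77, adjusted p = 0.000901 and 0.00105) and the tissue difference did not (-1.04, adjusted p = 1). None of the 3 passed over all genes with either tool.

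The first pattern weighed is the calls on neighbouring identifiers of chromosomes 10 and 7; if reads of the SUN transcript were counted on Solyc10g079250, its rise would be 1 fixed share of the SUN rise, and the share averaged 0.275 (SD 0.102) over the 5 pericarp days, 0.267 (SD 0.149) over the 4 columella days and 0.663 (SD 0.567) over the 5 seed days. The share was alike in pericarp and columella, and the difference between seeds and pericarp, which an exact permutation test, two-sided, left open (p = 0.0794), rests partly on 10 dpa, without which the seed share was 0.415. For Solyc10g079210 miscounted SUN reads stay open, as the differences lay 0.239 standard errors above the rise predicted from pericarp in seeds (predicted 0.795, observed 1.12, SE 1.38 CPM) and -1.20 standard errors from it in columella (predicted 1.02, observed 0.442, SE 0.486 CPM). A sequence difference in the NIL that hides a fixed share of reads would lower Solyc07g007750 and Solyc07g007760 by the same log2 amount in every tissue; instead the falls differed between tissues in both limma and edgeR (larger adjusted p of the 2 tools 0.00174 and 0.000568, over 6 tests), though these 2 identifiers were picked because they were called, and over all genes the limma adjusted p of these differences was 0.454 and 0.222. A hypothesis that stays open, untested for lack of coordinates, is that the inserted copy carried neighbours of SUN with it and altered the genes at its insertion site.

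The second pattern is the 131 calls in columella at 2 dpa. Thinning 1 wild type library of another tissue and day to 180921 reads, for 26 libraries in turn, gave a median of 18.5 identifiers called higher in SUN NIL (at most 4 before thinning and up to 631 after), and at least 126 for 4 libraries. Low depth in 1 library could therefore give such a list in some libraries and falls short of it in most. A genotype effect at 2 dpa would also show against wild type replicate 1 alone. There 35.7% of the 126 identifiers kept at least 50% of their fitted log2 difference, too few or too many to decide. The 126 were called with the same libraries, which favours a difference there. In the shallow library 89.7% of them had no read, against 23.6% of all tested identifiers, but low values there also helped to select them. Without the 2 doubted columella libraries 3 of the 131 were still called, so depth does not account for these; for the others depth and genotype cannot be told apart, because the shallow library is 1 of only 2 wild type samples.

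The third pattern is wild type columella at 4 dpa replicate 1, whose nearest library was wild type seeds at 6 dpa replicate 2 (r = 0.939 across genes, which are not independent replicates) and not columella of its own day (median r = 0.899); that seed library was itself low in seed-high genes, at a share of 0.607 of the other seed libraries of its day. Seed material in it would raise seed-high genes. Over 76 such genes its share of the seed level at 4 dpa was -0.00652. That lies within the range of the other columella libraries of that day and argues against a typical seed library under its label. The seed part also held placenta, and placenta with few seeds was not tested, so such material stays open. Pericarp material would raise pericarp-high genes, and the share over 46 of them was -0.0284. Older fruits would move it towards 8 dpa in rising and falling genes alike; the shares of the way were 0.0584 over genes higher at 8 dpa and 0.362 over genes lower at 8 dpa, and the first lies within the range of the other libraries. It lacked columella-high genes (share of the way to seeds 0.887) without gaining seed-high or pericarp-high genes. No biological explanation other than age was tested.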

How the results depend on the processing

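The edgeR and voom fits and the fit without the 2 doubted columella libraries were chosen after the data were seen. No called difference of a named gene changed sign. With TMM scaling the surplus of lower genes between 10 and 2 dpa turned into a surplus of higher ones in each tissue (5084 higher and 3040 lower in columella), and with edgeR the uncalled SUN difference of columella minus pericarp turned from -0.79 to 0.32. Among single genes, 2948 values kept their side of the threshold, 41 lost it and 20 gained it; SUN in seeds minus pericarp gained it in 11 of 54 fits. Moved counts follow; their cause was not tested except where fewer samples or genes entered. Total calls over the 14 tissues and days were 762 (pseudocount 0.25), 68 (pseudocount 5), 615 (no filter), 47 (quantile), 52 (quality weights), 41 (only the samples compared), 44 (edgeR) and 58 (without the 2 doubted columella libraries). Seeds minus pericarp gave 1 (pseudocount 0.25), 3 (pseudocount 5), 2 (quality weights), 3 (only the samples compared), 1 (edgeR), 1 (voom) and 2 (without the 2 doubted columella libraries). Columella minus pericarp gave 2 (pseudocount 0.25), 1 (pseudocount 5), 1 (TMM), 1 (quantile), 1 (only the samples compared) and 2 (edgeR). With no filter, pericarp genotype calls were 15, the change with day 4 in pericarp and 17 in seeds, and chromosome 7 calls 4. The change with day in pericarp gave 0 (quantile), 0 (only the samples compared) and 0 (edgeR). Genotype calls in columella were 3 (only the samples compared). With wild type only, columella against pericarp gave 4447, 10 against 2 dpa in pericarp 4524 and in seeds 4666.

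Replicate numbers were not used to pair the libraries in the main fit. Over 14 pairs of groups of 1 tissue and day the correlation of deviations had a median of 0.123 and a minimum of -0.596. Of these, 8 lay over 0.1 and 3 under -0.1. Over 26 pairs of tissues of 1 genotype and day the median was 0.0859, with 12 over 0.1 and 2 under -0.1. All 378 pairs of groups had a median of 0.00572, with 99 over 0.1 and 96 under -0.1. Some variation shared by equal replicate numbers can therefore not be excluded. With the replicate number as a fixed block, genotype calls were 8, 6 and 4 and the total over tissues and days 152; as a random block, seeds minus pericarp gave 1 and columella minus pericarp 1; SUN in seeds minus pericarp passed (limma adjusted p = 0.0238, range over its alternatives 8.45e-05 to 1).

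Leaving out 1 library at a time assumes that the lone replicate varies like other groups. The range was 48 to 3323 for the total over tissues and days, 5 to 596 for columella, 0 to 1 for seeds minus pericarp, 0 to 82 for columella minus pericarp, 0 to 34 for seeds minus columella, 0 to 1 for the change with day in pericarp, 0 to 847 in columella, and 2 to 49 for chromosome 7 calls. The highest values, 3323, 596, 82, 34, 847 and 49, came without wild type columella 2 dpa replicate 1, which leaves the 180921-read library alone; without wild type columella 4 dpa replicate 2 the total was 1493, columella 27 and its change with day 63, and without SUN NIL pericarp 10 dpa replicate 1 it was 1011. It was 115 without either SUN NIL pericarp 6 dpa library, 105 without wild type columella 10 dpa replicate 2, 52 without wild type columella 2 dpa replicate 2 or SUN NIL columella 2 dpa replicate 1, and 48 without SUN NIL columella 2 dpa replicate 2. Pericarp and seed genotype calls stayed within 7 to 9 and at 4. Counts near 0 also moved: columella minus pericarp gave 6 without wild type columella 4 dpa replicate 2 and 1 without SUN NIL pericarp 2 or 10 dpa replicate 2 or wild type pericarp 8 dpa replicate 1; seeds minus columella gave 1 without wild type columella 4 dpa replicate 1 or SUN NIL columella 4 dpa replicate 2; seeds minus pericarp gave 1 without any 1 of 7 libraries. An absent gene can lie at up to 16.6 CPM in the shallowest library, which limits what 2 dpa columella can show.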

Other observations

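The tests on other splits and on seeds at 6 dpa were chosen only after the results were seen. Seeds at 6 dpa divided across genotypes. Wild type replicate 1 correlated best with SUN NIL replicate 2 (r = 0.969 across genes) and wild type replicate 2 with SUN NIL replicate 1 (r = 0.970), against 0.937 and 0.928 between replicates of 1 genotype. Over 94 seed-high genes wild type replicate 2 reached a share of 0.607 of the level of the other seed libraries of that day, and the remaining 3 lay between 0.981 and 1.02. Solyc12g082730, next in identifier order to Solyc12g082720, had log2 genotype differences of -0.98, -0.38 and -1.22 in pericarp, columella and seeds, none passing (limma adjusted p = 1, 0.842 and 1), beside -1.36, -0.62 and -1.08 of its neighbour.

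A hypothesis written before its result was seen was that SUN NIL fruits run ahead of or behind wild type in development. An age score was built in each tissue from the genes called between 10 and 2 dpa and scaled to days in wild type. SUN NIL lay 0.289 days ahead in pericarp (SD over 5 days 0.550, ahead at 4 of 5), 0.142 days in columella (SD over 4 days 0.920, ahead at 1 of 4) and 0.133 days in seeds (SD over 5 days 0.581, ahead at 3 of 5). Exact permutation tests within days, two-sided, gave adjusted p = 0.585, 0.832 and 0.832. The mean difference plus its SD over days stayed below a full day in pericarp and seeds and exceeded it in columella. That sum is not a confidence limit, so it does not exclude a shift of a full day in any tissue.

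Other splits of the same libraries were compared with the real ones. For the genotype effect in pericarp, 1 of 100 splits, the real one, gave as many as 8 calls (highest other 1). Chance is therefore an unlikely source of that count. The 8 include SUN, which defines the line, and the test of a count says nothing about single calls. In columella 10 of 100 splits gave 6 calls or more (highest other 29) and in seeds 9 of 100 gave 4 or more (highest other 1034), so by count alone chance cannot be excluded. A split with 1034 calls points to a structure of the seed samples, whose source was not examined. For the 0 calls between tissues 100 of 100 splits gave as many, as any split must, so this tests nothing (highest others 1131, just over 100 and 44 for seeds minus pericarp, columella minus pericarp and seeds minus columella). For the change with day, 5 of 100 splits gave the 1 call of pericarp (highest other 1), and the 0 calls of columella and seeds again test nothing (highest others 36 and 57). For the tissues 1 of 100 splits, the real one, gave as many calls (10038, 7038 and 7327, highest others 58, 772 and 2625). Chance is an unlikely source of these counts. For 10 against 2 dpa, fitted without genotype, the same held for 1 of 35 splits (7790, 8260 and 7868 calls in pericarp, columella and seeds, highest others 3362, 1644 and 6121); splits that exchange few libraries keep part of the difference between days.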
